A study of Mus musculus with 9 samples.

How the data were processed

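Total RNA of spleen from 9 samples in 3 groups of 3 had been labelled and hybridised to Agilent whole-genome mouse arrays (design 026655) by the manufacturer's 1-colour protocol, per the labels' protocols. Groups and replicate numbers were taken from the labels alone. How the disease was brought about and how the diets were made up are not given in the sources used here.

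The deposited scanner files hold an intensity per spot on a linear scale, made with Agilent Feature Extraction 11.0.1.1, per the file headers, which give background subtraction and spatial detrending for the processed signal and no scaling between arrays. Spots near background carry a surrogate value there. The 0 or 1 marks for well above background, saturation and outlier spots come from the same deposited files. A table of log2 values deposited by the authors for the whole series was used only as an alternative. How it was made is not given in the sources used here. Its 9 columns share 1 distribution with a median of 6.43, as quantile-normalized values would, it is not centred per gene, and 39485 probes are in it. Set against the scanner signals by rank correlation across probes, 6 of the 9 columns matched their own array best. The 3 low Se non-GD columns each matched another array of the same group best (0.997 to 0.998, against 0.980 to 0.987 for the array of the same label), so that the replicate numbers of that group are uncertain, while its membership is not affected.

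Each array held 44397 spots, of which 1377 control spots were left out of the tests. Processed signals were taken as log2 and each array's 75th percentile over the 43020 non-control spots was subtracted. Spots with a non-uniformity or population outlier mark were left out, spots of 1 probe were averaged, and each gene was represented by the probe with the highest mean over the 9 arrays. Gene names came from matching the accession of each probe, without versions, to a table of the GRCm38.p6 annotation, which named 27234 of 39429 probes. The other 12195 kept the identifier of the array design. No coordinates are given, since the array design was annotated on another build. Of 32451 genes or accessions, 6078 were left out as well above background on fewer than 3 of the 9 arrays and 48 because a marked spot left an array without a value, and 26325 were tested, 17506 of them with a symbol. No spot was saturated (0 on every array). Among genes named in a comparison and with several probes, probes were called in opposite directions for Gmps, Eaf2 and Klra7 in the comparison of low Se GD with low Se non-GD (the first), and for Gmps, Klra7 and Foxm1 in that of normal Se GD with low Se non-GD (the third). The second comparison is normal Se GD against low Se GD. In the third this was also so for Gbp6, Ccdc92b and Srebf2, which the naming rule took for other comparisons. Fold changes of both signs were seen for 12 of 38, 7 of 43 and 9 of 38 such genes in the 3 comparisons in order. A gene well above background on no array of 1 group is given as "at least N-fold". That bound sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the lowest signal well above background on the array and the gene's own signal.

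Comparisons were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with all 9 arrays in 1 fit, 6 residual degrees of freedom and 1.81 prior ones. P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Fold changes are log2 differences between group means with their standard errors, and ± gives the SD over n = 3 arrays. Fixed lists of genes, 37 in number, for selenium biology, thyroid hormone, spleen cell types, neighbouring tissues, inflammation, stress, proliferation and metabolism, were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 36 lists with at least 3 measured members. The immunoglobulin list could not be tested for lack of such members. Camera was also run with an estimated correlation, under which 0 lists passed in any comparison (2, 7 and 3 at an unadjusted p), against 13, 17 and 8 with the preset value. For some lists the estimate was below the preset value, as for selenoproteins (-0.0123), natural killer markers (-0.0269) and stromal genes (-0.0014). Where such a list lost its call, movement of its own members together was not the reason. The unadjusted camera p of selenoproteins in the first comparison went from 0.00409 with the preset value to 0.0190 with the estimate. The adjusted p of a list also depends on the p of the other lists, whose estimates reached 0.839 for cell cycle genes. Fry, which asks only whether a list's own genes move one way, passed 16, 13 and 20. Genes to be named were drawn, per comparison, from up to 12 higher and 12 lower genes with the largest change among those past the threshold whose groups do not overlap and whose name is a gene symbol. Added to these were every measured selenoprotein in the first 2 comparisons and the 4 members of a list with the smallest p. Some genes that this rule takes are not reported here. The design, this rule, the lists and the first set of other settings were fixed before the data were examined. Members are said to rise or fall only where they passed over all genes, and counts adjusted over the list alone stand beside them.

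The steps were tested on simulated data for 26325 genes with 200 changed. Of 100 genes changed 2-fold, 42, 53 and 51 were recovered in the 3 comparisons in order, and of 100 changed 4-fold 70, 70 and 81, with 4, 8 and 7 false calls. Noise was drawn independently for each gene and array. These rates need not hold for the real arrays, whose genes and slides are correlated.

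Other settings were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, the percentile over probes above background on all arrays, and the authors' table. For the choice of spots and probes they were no filter or a stricter filter on dim probes, outlier spots kept, and all probes or their mean. For the fit they were only the 2 groups compared, a variance trend with robust estimation, array weights, replicate number or slide as a block, other thresholds, and leaving out each array. Normexp used the median signal of spot and background. Scanning took place on 1 day, so no scan date block was run. After the data were seen, runs were added without the arrays that stood apart, within slides 1 and 2, with slide as a random block and with the E1A control spot as a covariate. The covariate was centred within groups, so it could change the spread but no fold change, and it does not adjust a difference between groups for E1A. That spot is for a viral sequence that is not part of the mouse genome. Array weights by limma's default did not converge: low Se GD replicate 2 took 99.2% of all weight, and the gene-by-gene method was used in its place after that was seen. It too put most weight on 2 arrays, 54.1% on low Se non-GD replicate 3 and 31.5% on low Se GD replicate 2. A gene or list passing under neither setting was counted as unchanged between them, whatever its sign.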

Results

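Gene expression in the spleen of female BALB/c mice was measured on 9 Agilent 1-colour arrays, 1 array per sample, in 3 groups of 3 samples. The groups were mice without Graves' disease on a low selenium supply (low Se non-GD), mice with Graves' disease on a low selenium supply (low Se GD) and mice with Graves' disease on a normal supply (normal Se GD). Graves' disease is an autoimmune disorder in which antibodies stimulate the thyrotropin receptor and the thyroid overproduces hormone. Selenium is built into selenoproteins, among them glutathione peroxidases, thioredoxin reductases and the deiodinases that activate or inactivate thyroid hormone. By its title, the study asks how selenium intake bears on this disease. No group combined a normal supply with the absence of disease, so selenium could be compared within diseased mice only and no interaction could be tested. The labels do not say whether the samples of a group came from separate animals, so all p-values measure the spread between these samples, which may be technical.

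Of 43020 non-control spots per array, between 72.6% and 82.6% were well above background on 8 arrays, and 58.4% on the array of normal Se GD replicate 3. Slide 1 held the 3 low Se non-GD arrays and low Se GD replicate 1, slide 2 held low Se GD replicates 2 and 3 with normal Se GD replicates 1 and 2, and normal Se GD replicate 3 was alone on slide 3. Correlations across genes between arrays of 1 group lay between 0.982 and 0.992 for low Se non-GD, 0.986 and 0.995 for low Se GD, and 0.963 and 0.994 for normal Se GD. Low Se non-GD replicate 3 and low Se GD replicate 2 lay between the other 2 arrays of their group for 78.3% and 69.0% of the 18538 genes above background on all arrays, where the 3 arrays of a group average 33.3%. For genes at least 2-fold apart between the other 2 arrays, a choice that itself raises the share, it was 98.6% and 97.1%. The E1A control spot a107 averaged 5.30 ± 0.56 in low Se non-GD, 1.73 ± 0.75 in low Se GD and 1.53 ± 0.77 in normal Se GD (log2 signal minus the array's 75th percentile, SD, n = 3 each). A signal named Rn28s1, for large-subunit ribosomal RNA, lay between 0.45 and 0.83 in low Se non-GD and between 3.003 and 5.99 on the 6 GD arrays. The number of arrays, 3 per group, limited the precision of every comparison. They were tested as separate samples, which stays open for the 2 in-between arrays.

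The first comparison, low Se GD against low Se non-GD, addressed the disease state at a fixed low selenium supply. As lists, interferon-stimulated and macrophage genes were higher in the diseased spleens, and B cell markers were lower. These 3 lists passed camera with a preset correlation but not with an estimated one (adjusted p = 0.890 for each). Ifit1, an antiviral RNA-binding protein induced by interferon, stood at 1.77 ± 0.10 in low Se GD against -1.26 ± 0.57 in low Se non-GD, a log2 fold change of 3.03 (SE 0.29, adjusted p = 0.000824). The complement chains C1qa and C1qc, made in spleen mainly by macrophages, rose by 1.46 (SE 0.15, adjusted p = 0.00107) and 1.30 (SE 0.18, adjusted p = 0.00287). Fcer2a, the low-affinity IgE receptor of mature B cells, fell by 0.96 (SE 0.11, adjusted p = 0.00172), from 0.84 ± 0.09 to -0.12 ± 0.02. Selenop, the selenium transport protein of plasma, rose by 1.24 (SE 0.21, adjusted p = 0.00522). These changes are log2 differences over 3 arrays per group, and the 3 values of 1 group lay wholly above those of the other for each of these 5 genes.

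Interferon-stimulated genes had the smallest adjusted p of all lists under camera at the preset correlation. By fry other lists had smaller ones, such as selenoproteins (adjusted p = 0.000537, against 0.0154 for the interferon list). Of 33 measured members, 19 rose and 1 fell (24 and 1 adjusted over the list alone), with a median log2 fold change of 1.04 (camera adjusted p = 1.23e-06). The other members named by the rule were Rtp4, a chaperone of receptors that interferon induces (2.02, SE 0.28, adjusted p = 0.00267), Ifi27l2a (1.35, SE 0.16, adjusted p = 0.00186) and Gbp6, a guanylate-binding protein (-2.24, SE 0.29, adjusted p = 0.00231). Gbp6 was the member that fell, with a second probe at 0.18 that was not called, and it belonged to the 1299 genes whose fitted change was at least 4-fold lower, which followed the E1A control spot between arrays of 1 group. The list's adjusted p was 0.890 with an estimated correlation, and ranged from 1.32e-08 to that value over the camera alternatives. Slide 1 held 1 low Se GD array, so that in this comparison the values with slide as a block and within slide 1 rest on that array and assume that it varies like the others. They gave a median of 0.87, with adjusted p of 0.000119 and 3.08e-05.

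Macrophage lists moved the same way. Among 19 monocyte and macrophage markers 10 rose and 3 fell (10 and 3 adjusted over the list alone), with a median of 0.58 and an adjusted p of 0.0210. Cd14, the co-receptor for bacterial lipopolysaccharide, rose by 1.01 (SE 0.10, adjusted p = 0.000815) and Csf1r, the receptor for the macrophage growth factor, by 0.70 (SE 0.10, adjusted p = 0.00334). Of the 3 probes of Csf1r only 1 was called, and the lowest stood at 0.20. Of 13 genes of red pulp macrophages and iron recycling, 4 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.59, or 0.48 with 1 member set to its bound; adjusted p = 0.0210). They were the adhesion molecule Vcam1 (1.02, adjusted p = 0.00233), the iron exporter Slc40a1 (1.06, adjusted p = 0.0208), Slc11a1 (0.74, adjusted p = 0.00732) and Hpgd (0.83, adjusted p = 0.0202). Natural killer and cytotoxic cell markers showed 9 members that rose and 1 that fell of 19 (12 and 1 adjusted over the list alone; median 0.49, adjusted p = 0.0210). Klra8 (0.79, adjusted p = 0.00478), Klrd1 (0.70, adjusted p = 0.00695) and the granule protein Nkg7 (0.49, adjusted p = 0.00761) rose, while Klra7 (-3.46, adjusted p = 0.00667) fell. Probes of Klra7 were called both ways, and Klra8 stood at -0.03 as the mean of its probes. With an estimated correlation the adjusted p was 0.890 for both macrophage lists and 0.407 for the natural killer list. With slide as a block the medians were 0.38, 0.51 and 0.40 with adjusted p of 0.579, 0.412 and 0.412, and within slide 1 the adjusted p was 0.634, 0.490 and 0.490. Leaving out 1 array ended the call of macrophage markers without low Se GD replicate 3 (0.50, adjusted p = 0.0564), of red pulp genes without low Se non-GD replicate 2 (0.32, adjusted p = 0.0622) and of natural killer markers without normal Se GD replicate 3 (0.49, adjusted p = 0.0720). Over the camera alternatives the adjusted p ran from 0.00448, 0.000879 and 0.00470 to 0.890, 0.890 and 0.490.

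B cell markers were lower as a list. Of 20 measured, 0 rose and 6 fell (1 and 10 adjusted over the list alone; median -0.26, adjusted p = 0.00596). Besides Fcer2a, the complement receptor Cr2 fell by 0.77 (SE 0.16, adjusted p = 0.0112). The exchange factor Ralgps2 fell by 0.68 (SE 0.11, adjusted p = 0.00405) and the kinase Blk, which acts in B cell receptor signalling, by 0.61 (SE 0.10, adjusted p = 0.00505). The list of inflammatory cytokines and NF-kB targets had 0 members that rose and 3 that fell of 18 (0 and 3 adjusted over the list alone; median -0.23, adjusted p = 0.0210). These were Nfkbiz, a nuclear regulator of NF-kB (-0.62, adjusted p = 0.00526), Birc3 (-0.38, adjusted p = 0.0300) and the neutrophil-attracting chemokine Cxcl1 (-3.30, adjusted p = 0.00667), which was also among the genes at least 4-fold lower. With an estimated correlation the adjusted p was 0.890 for both lists. With slide as a block the B cell median was -0.34 (adjusted p = 0.0358, and 0.0636 within slide 1) and the NF-kB median -0.47 (adjusted p = 0.000403, and 0.000477 within slide 1). The NF-kB list lost its call without low Se non-GD replicate 2 (-0.23, adjusted p = 0.0549) or low Se GD replicate 1 (-0.16, adjusted p = 0.180), and its median was -0.39 without low Se GD replicate 3. Over the camera alternatives the adjusted p ran from 0.000879 to 0.890 for B cell markers and from 0.000403 to 0.890 for the NF-kB list.

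All 24 selenoproteins were measured, of which 8 rose and 2 fell (9 and 2 adjusted over the list alone; median 0.29, adjusted p = 0.0210, but 0.407 with an estimated correlation). The plasma glutathione peroxidase Gpx3 rose by 1.49 (SE 0.38, adjusted p = 0.0247) and the cytosolic Gpx1 by 0.89 (SE 0.26, adjusted p = 0.0434). Sephs2, which makes the selenium donor for selenocysteine, rose by 1.60 (SE 0.41, adjusted p = 0.0244; well above background on 2 of 3 low Se non-GD arrays). The methionine sulfoxide reductase Msrb1 rose by 0.60 (SE 0.10, adjusted p = 0.00480), Selenoi by 0.63, Selenom by 0.46 and Selenok by 0.34. Dio3, the deiodinase that inactivates thyroid hormone, fell by 0.98 (SE 0.15, adjusted p = 0.00405) and Selenos by 0.57 (SE 0.16, adjusted p = 0.0392). The other 14 did not pass, among them Gpx4 (0.27, adjusted p = 0.139), Txnrd1 (0.27, adjusted p = 0.105), Selenow (-0.05, adjusted p = 0.879) and Selenoh (0.00, adjusted p = 0.981). The list's adjusted p was 0.0926 with slide as a block (median 0.27) and 0.0636 within slide 1, and ranged from 0.00448 to 0.407 over the camera alternatives. Of the 4 selenoproteins most sensitive to selenium supply, Gpx1 and Msrb1 rose and the list of 4 did not pass (median 0.30, adjusted p = 0.390). Of 17 genes of selenoprotein synthesis and selenium handling, Scly (0.48) and Selenbp1 (0.77) rose and Lrp8 fell by 0.92 (2 and 1 adjusted over the list alone; median 0.03, adjusted p = 0.944).

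**Figure D1:**
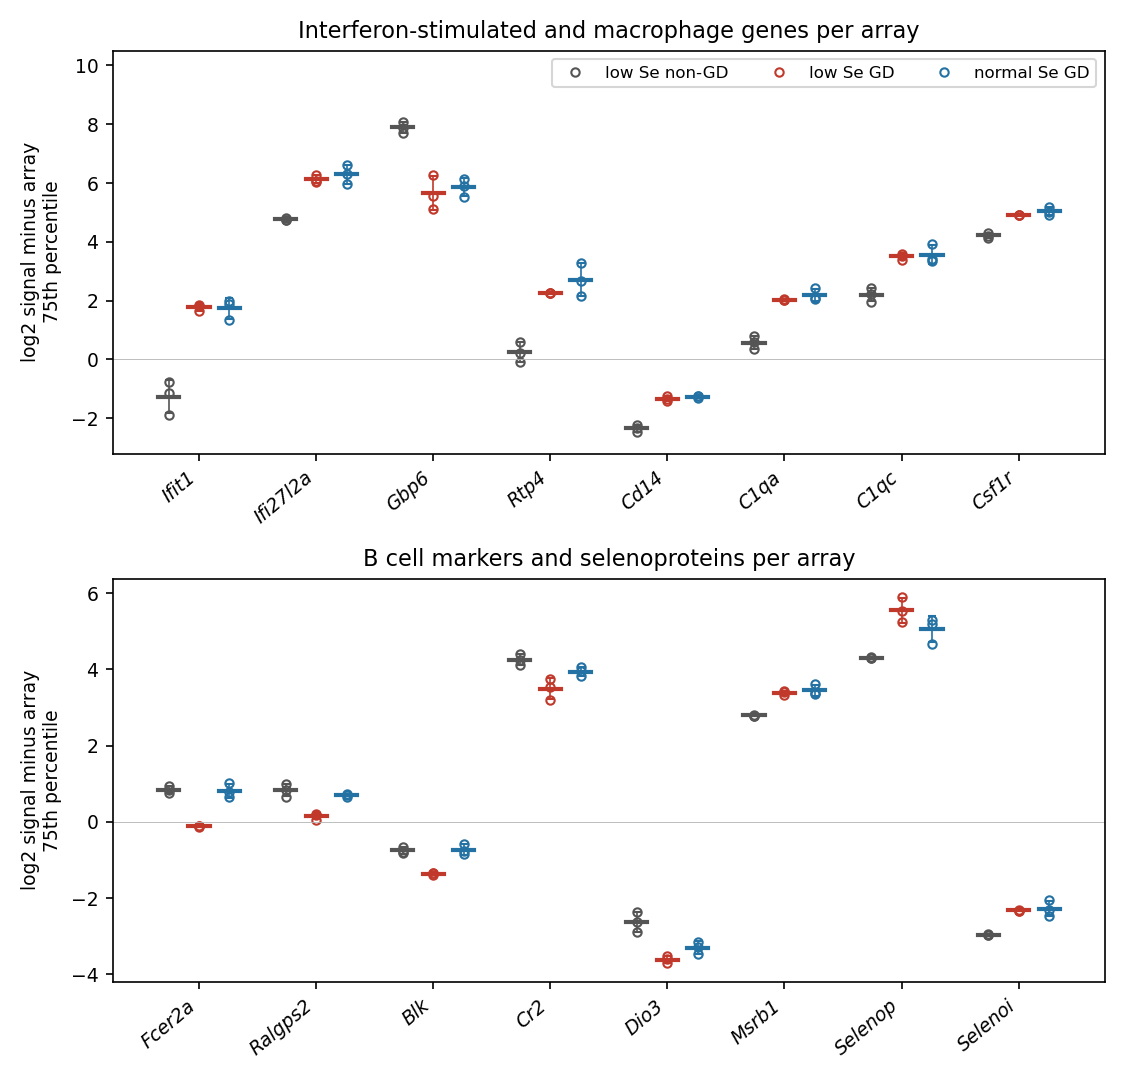
Each open circle is 1 array, with the group mean (bar) and SD (error bar) over 3 arrays, in log2 signal minus the array's 75th percentile. Ifit1 averaged -1.26 in low Se non-GD (grey) and 1.77 in low Se GD (red), and Fcer2a stood at 0.84, -0.12 and 0.82 in low Se non-GD, low Se GD and normal Se GD (blue).

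Erythroid genes were higher as a list in low Se GD (4 of 39 rose, 0 fell; 0 and 0 adjusted over the list alone; median 0.66, adjusted p = 0.0210). Cell cycle genes were so too (4 of 42 rose, 0 fell; 0 and 0 adjusted over the list alone; median 0.63, adjusted p = 0.00280). The erythroid members that rose were Mgst3 (1.98, adjusted p = 0.0123), Tspan8 (1.46, adjusted p = 0.0243), Tmcc2 (1.32, adjusted p = 0.0422) and the cell cycle regulator E2f2 (0.88, adjusted p = 0.0459). The cell cycle members were the replication helicase subunits Mcm2 (0.83, adjusted p = 0.0369), Mcm3 (0.66, adjusted p = 0.0186) and Mcm7 (0.94, adjusted p = 0.0271), and the centromere histone Cenpa (0.99, adjusted p = 0.0327). Megakaryocyte and platelet genes (5 of 20 rose, 0 fell; 5 and 0 adjusted over the list alone; median 0.27, adjusted p = 0.0318) included Thbs1 (1.44, adjusted p = 0.00201) and the platelet chemokine Ppbp (1.19, adjusted p = 0.00957). Subunits of mitochondrial complex I shifted by a median of 0.14 (8 of 37 rose, 0 fell; 8 and 0 adjusted over the list alone; adjusted p = 0.0264), with Ndufc2 at 0.72 and Ndufa4 at 0.73. Ribosomal proteins shifted by -0.14 (4 of 80 rose and 6 fell; 1 and 3 adjusted over the list alone; adjusted p = 0.0226), but by 0.25, 0.28 and 0.29 under normexp, quantile normalization and the authors' table. Their direction thus depended on the scaling. With an estimated correlation the adjusted p was 0.891 for these 5 lists, the highest over the camera alternatives, and the lowest was 3.66e-06, 3.05e-07, 0.00303, 0.00746 and 3.73e-05 in the order given. With slide as a block the medians were 0.37, 0.21, 0.13, 0.08 and -0.01, with adjusted p of 0.662 for the first 4 and 0.694 for the last, and 0.711 for each within slide 1. Without low Se non-GD replicate 2 none of the 5 passed, at medians of 0.24, 0.33, 0.11, 0.14 and -0.10 with adjusted p of 0.286, 0.0622, 0.188, 0.0622 and 0.145. Without low Se GD replicate 3 the calls of erythroid genes (0.55, adjusted p = 0.0869), megakaryocyte genes (0.22, adjusted p = 0.138), complex I (0.13, adjusted p = 0.138) and ribosomal proteins (-0.11, adjusted p = 0.0564) were lost. The call of ribosomal proteins was also lost without low Se GD replicate 2 (-0.11, adjusted p = 0.120). Without normal Se GD replicate 3 erythroid and megakaryocyte genes did not pass (0.66 and 0.27, adjusted p = 0.0831 for both), and without low Se non-GD replicate 1 their medians were 1.002 and 0.47.

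Fat tissue genes showed the widest shift, a median of 2.10, or 1.75 with 2 members set to their bound (5 of 12 rose and 1 fell; 8 and 1 adjusted over the list alone; adjusted p = 0.0253). The fatty acid carrier Fabp4 rose by 3.91 (SE 0.97, adjusted p = 0.0223) and the adipocyte hormone Adipoq by 3.51 (SE 0.98, adjusted p = 0.0343; well above background on 2 of 3 low Se non-GD arrays). Cidec rose by 2.26 (SE 0.43, adjusted p = 0.00790) and Plin1 at least 2.93-fold (adjusted p = 0.0222). Lipe, a lipase of fat cells, fell by 1.91 (SE 0.51, adjusted p = 0.0296). Fabp4 varied widely within the groups, at 5.50, 4.46 and 2.11 on the low Se GD arrays and 1.38, -1.63 and 0.57 on the low Se non-GD arrays. The list's adjusted p was 0.890 with an estimated correlation, 0.0358 with slide as a block (median 3.13) and 0.00910 within slide 1, both resting on low Se GD replicate 1, the array with the highest Fabp4. It ranged from 0.00107 to 0.890 over the camera alternatives. The median ranged from 1.06, with normexp, to 3.13. The call of the fat tissue genes was lost without low Se non-GD replicate 2 (1.92, adjusted p = 0.0622), without low Se GD replicate 1 (1.59, adjusted p = 0.0585) and without normal Se GD replicate 3 (2.10, adjusted p = 0.105).

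Of the 23 lists that did not pass, several held members with large changes. In the list of thyroid hormone signalling 4 of 19 rose and 3 fell (4 and 3 adjusted over the list alone; median 0.27, adjusted p = 0.396). The thyroid hormone receptor Thrb rose by 1.22 (SE 0.14, adjusted p = 0.00149) and the corepressor Hr by 1.67 (SE 0.17, adjusted p = 0.00101). The carrier Ttr was at least 6.62-fold lower (adjusted p = 0.00452) and was among the genes at least 4-fold lower. Of 29 NRF2 targets and antioxidant enzymes 4 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.27, adjusted p = 0.0885): Gsr, which recycles glutathione (0.94, adjusted p = 0.000889), Me1 (1.06), Prdx1 (0.40) and Pgd (0.36). Plasma cell markers had a median of 0.33 (7 of 20 rose, 1 fell; 8 and 1 adjusted over the list alone; adjusted p = 0.0885), with Sdf2l1 at 0.88 and Xbp1, a transcription factor of secretory cells, at 0.74. Dendritic cell markers had a median of 0.33 (7 of 18 rose, 1 fell; 9 and 1 adjusted over the list alone; adjusted p = 0.0961). Medians and adjusted p of other lists were -0.05 and 0.453 for T cell markers and -0.16 and 0.471 for regulatory T cells. They were -0.04 and 0.928, 0.21 and 0.347, and 0.13 and 0.822 for T helper 1, 2 and 17 genes, and 0.12 and 0.401 for germinal centre B cells. They were 0.25 and 0.390 for neutrophils, 0.29 and 0.454 for mast cells, basophils and eosinophils, and 0.05 and 0.944 for pancreas. They were 0.13 and 0.453 for complement and acute phase genes, 0.06 and 0.944 for antigen presentation by MHC class II, 0.19 and 0.453 for immediate early genes, 0.16 and 0.695 for cholesterol and fatty acid synthesis, and 0.05 and 0.870 for circadian clock genes. Median, mean and test differed in sign for the immediate early (mean -0.06), T helper 1 (mean 0.00), T helper 17 (mean -0.02) and pancreas (mean -0.09) lists, and the MHC class II list tested down with a median above 0. With members at their bound the medians were 0.19 for neutrophils, 0.02 for pancreas, 0.12 for complement, 0.17 for immediate early and 0.00 for clock genes.

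In all, 6556 of 26325 genes passed in this comparison, 3357 higher and 3199 lower, and groups did not overlap for 53% of all genes against 10% by chance. Large changes were unequal in direction: by the fitted value 60 genes were at least 4-fold higher and 1299 at least 4-fold lower. Of these, 26 and 103 were above background on no array of the dimmer group and have only a bound. With bounds in place of fitted values, 35 were at least 4-fold higher and 1258 at least 4-fold lower. Among the higher genes the rule named Cbr2 (3.92, SE 0.33, adjusted p = 0.000575), Rn28s1 (3.62, SE 0.59, adjusted p = 0.00472) and Gfra4 (3.02, SE 0.59, adjusted p = 0.00904). Rn28s1 is ribosomal RNA, and whether its shift bears on the other calls was not tested. Of the 3 probes of Gfra4 only 1 was called, and the lowest stood at 0.48. The rule also named Thrsp (2.87), Ptgis (2.81), Mc3r (2.79) and Cox8b (2.64). Cyp2f2, a cytochrome P450 (at least 9.35-fold, adjusted p = 0.00210), and Sv2c (at least 1.34-fold) were named by their fitted value but, not well above background in low Se non-GD, have no rank. Among the lower genes were Slc24a2 (-4.71, SE 0.60, adjusted p = 0.00215, with its other probe at 0.20 and not called), Svop (-4.53), Tmem121b (at least 11.5-fold), Ceacam5 (at least 8.39-fold), Acp4 (at least 6.45-fold) and Syt14 (-4.30). Further ones were the pheromone receptor Vmn1r174 (-4.22, SE 0.17, adjusted p = 4.58e-05), Prss32 (-4.17), Tmem169 (-4.14), Abcc6 (-4.13) and the odorant receptor Olfr71 (-4.13). Gmps was named at -4.15, but 2 of its 3 probes were called higher and 1 lower. The 1299 genes with a fitted change of at least 4-fold lower followed the E1A control spot between arrays of 1 group (median correlation 0.782). They were low on all 6 GD arrays. Whether called genes with smaller falls, such as Dio3 and Lipe, also followed this spot was not tested.

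**Figure D2:**
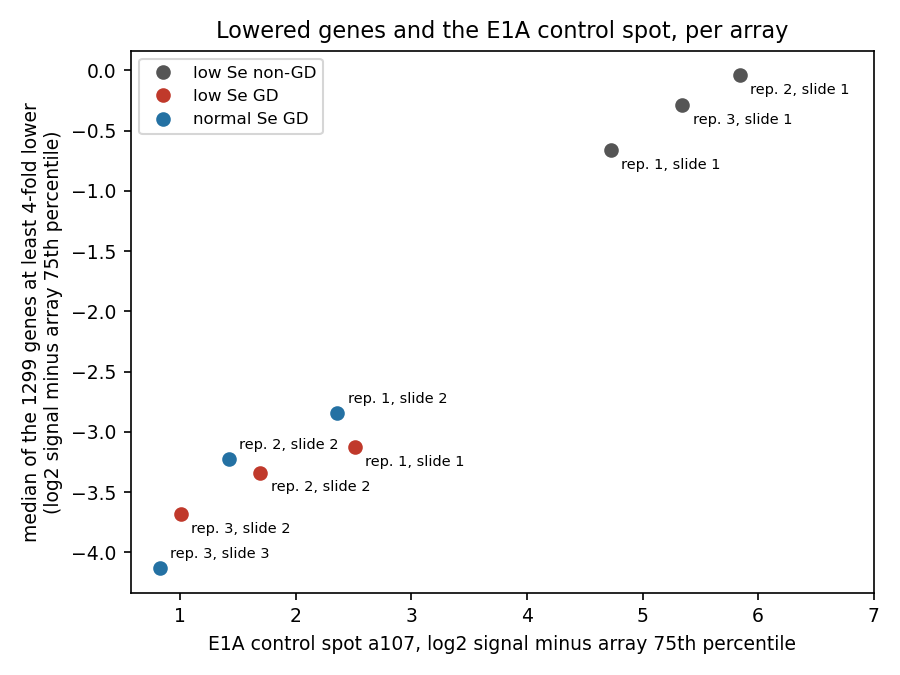
Each point is 1 array: the level of the E1A control spot a107 on the horizontal axis and the median of the 1299 genes with a fitted change of at least 4-fold lower in low Se GD than in low Se non-GD on the vertical axis, both in log2 signal minus the array's 75th percentile. The low Se non-GD arrays (grey) lay between 4.72 and 5.84 on the control spot and between -0.66 and -0.04 on the genes, and low Se GD replicate 1, on the same slide, lay at 2.51 and -3.13.

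The count of 6556 was 7444 with slide as a block and 940 within slide 1, where a single low Se GD array remained. It was 269 without the 2 in-between arrays, 2929 without these and normal Se GD replicate 3, 3448 without low Se GD replicate 2, 4352 and 3547 without low Se non-GD replicates 2 and 3, and 10787 without normal Se GD replicate 3.

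The second comparison, normal Se GD against low Se GD, addressed selenium supply within diseased mice. As lists, B cell and antigen presentation genes were higher with normal selenium, and genes of red cell precursors, of dividing cells and of fat tissue were lower. With an estimated correlation none of these 5 lists passed (adjusted p = 0.242, 0.242, 0.458, 0.458 and 0.272 in that order). Fcer2a rose by 0.94 (SE 0.11, adjusted p = 0.0369), from -0.12 ± 0.02 to 0.82 ± 0.18, Blk by 0.64 (SE 0.10, adjusted p = 0.0438) and the B cell scaffold Bank1 by 0.52 (SE 0.09, adjusted p = 0.0441). The actin-bundling protein Fscn1 of mature dendritic cells rose by 0.87 (SE 0.11, adjusted p = 0.0369) and the integrin Itgax by 0.67 (SE 0.10, adjusted p = 0.0427). None of the 24 selenoproteins passed.

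For selenoproteins the limma count was 0 of 24, with 4 at an unadjusted p under the threshold (0 and 0 adjusted over the list alone; median 0.02 and mean -0.06, adjusted p = 0.643). Gpx1 changed by -0.22 (SE 0.26, adjusted p = 0.690), Selenop by -0.50 (SE 0.21, adjusted p = 0.245), Gpx3 by -0.57 (SE 0.38, adjusted p = 0.458) and Gpx4 by -0.26 (SE 0.12, adjusted p = 0.291). Txnrd2 had the smallest p (-0.90, SE 0.23, adjusted p = 0.0892). Selenow stood at 0.18 (adjusted p = 0.611), Msrb1 at 0.06 (adjusted p = 0.754) and Selenoh at -0.06 (adjusted p = 0.751), and the list of the 4 most sensitive selenoproteins had a median of 0.00 (adjusted p = 0.909). Selenoprotein synthesis and selenium handling genes had a median of -0.07 (0 of 17 passed, 4 unadjusted; 0 and 0 adjusted over the list alone; adjusted p = 0.643).

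B cell markers shifted by a median of 0.38 (3 of 20 rose, 0 fell; 12 and 0 adjusted over the list alone; adjusted p = 1.79e-06, and 0.000175 with slide as a block). Genes of antigen presentation by MHC class II shifted by 0.37 (2 of 15 rose, 0 fell; 6 and 0 adjusted over the list alone; adjusted p = 0.000254). The 2 were H2-DMa (0.53, adjusted p = 0.0411) and H2-DMb2 (0.85, adjusted p = 0.0435), parts of the complex that loads peptides. Dendritic cell markers shifted by 0.39 (3 of 18 rose, 0 fell; 9 and 1 adjusted over the list alone; adjusted p = 0.000361). The chemokine Ccl22 rose by 0.81 (adjusted p = 0.0438; above background on 2 of 3 arrays of each group). The NF-kB list shifted by 0.44 (1 of 18 rose, 0 fell; 7 and 0 adjusted over the list alone; adjusted p = 0.000361), with Nfkbiz at 0.68 (adjusted p = 0.0427) and Tnf at 0.98 (adjusted p = 0.0739). T helper 1 genes shifted by 0.39 (limma passed 0 of 14, 7 unadjusted; 7 and 0 adjusted over the list alone; adjusted p = 0.000639). With an estimated correlation the adjusted p was 0.242 for these 5 lists, the highest over their camera alternatives, and the lowest were 3.55e-11, 3.68e-07, 4.02e-05, 8.78e-06 and 8.31e-05. All 5 passed with slide as a block, with medians of 0.31, 0.24, 0.26, 0.29 and 0.34. Dendritic cell markers alone lost the call within slide 2 (adjusted p = 0.0601). Only slide 2 held arrays of both groups of this comparison. The fold changes with slide as a block are therefore those within slide 2, and the other arrays enter the spread only. These settings are not separate checks of the direction or size of a shift. Without low Se GD replicate 1 the MHC class II median was 0.22.

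Cell cycle genes shifted by a median of -0.78 (limma passed 0 of 42, 26 unadjusted; 0 rose and 12 fell adjusted over the list alone; adjusted p = 1.10e-14). Erythroid genes shifted by -0.99 (0 of 39 passed, 18 unadjusted; 0 rose and 15 fell adjusted over the list alone; adjusted p = 7.12e-11). Cell cycle members with the smallest p included Mcm3 (-0.77, adjusted p = 0.0629) and the cyclins Ccne1 (-1.14, adjusted p = 0.103) and Ccne2 (-1.82, adjusted p = 0.108). Erythroid ones were the membrane proteins Add2 (-1.21, adjusted p = 0.0556) and Aqp1 (-1.31, adjusted p = 0.0639) and the transcription factor Tal1 (-1.25, adjusted p = 0.0730). Both lists had an adjusted p of 0.458 with an estimated correlation, the highest over the camera alternatives, against lowest values of 2.77e-29 and 2.54e-21, and both kept their calls with slide as a block (medians -0.96 and -1.22). Complex I subunits shifted by -0.16 (0 of 37 passed, 13 unadjusted; 0 and 0 adjusted over the list alone; adjusted p = 0.000361). Their adjusted p was 0.458 with an estimated correlation and ranged from 1e-09 to 0.458 over the camera alternatives. Fat tissue genes shifted by -2.43, or -2.22 with 1 member set to its bound (0 of 12 rose and 1 fell; 0 and 9 adjusted over the list alone; adjusted p = 6.17e-07). The member that fell was Adipoq (-5.59, SE 0.98, adjusted p = 0.0448), followed by Fabp4 (-4.99, SE 0.97, adjusted p = 0.0559) and Car3 (-6.48, adjusted p = 0.0609). Fabp4 lay between -1.04 and -0.91 on the 3 normal Se GD arrays. The adjusted p of the fat list was 0.272 with an estimated correlation and 4.70e-05 with slide as a block (median -1.94), with a range of 4.26e-11 to 0.272 over the camera alternatives. Its median ranged from -3.15, without low Se GD replicate 3, to -0.41, over probes above background on all arrays, where it did not pass.

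A further 8 lists passed, and the slide block ended each of these calls. Stromal and endothelial genes shifted by a median of 0.33 (1 of 22 rose, 0 fell; 3 and 0 adjusted over the list alone; adjusted p = 0.000395), with the matrix proteoglycan Bgn at 0.80 (adjusted p = 0.0498). Plasma cell markers shifted by 0.24 (2 of 20 rose, 0 fell; 4 and 0 adjusted over the list alone; adjusted p = 0.00310). The 2 were the surface receptor Slamf7 (0.74, SE 0.09, adjusted p = 0.0369) and Sdf2l1 (0.69, SE 0.10, adjusted p = 0.0385). Macrophage markers shifted by 0.30 (1 of 19 rose, 0 fell; 1 and 0 adjusted over the list alone; adjusted p = 0.00310), with the scavenger receptor Marco at 0.64 (adjusted p = 0.0481). Interferon-stimulated genes had a median of 0.24 (0 of 33 passed, 8 unadjusted; 0 and 0 adjusted over the list alone; adjusted p = 0.00856). T helper 17 genes had a median of 0.27 (0 of 11 passed, 3 unadjusted; 0 and 0 adjusted over the list alone; adjusted p = 0.00996). Genes of cholesterol and fatty acid synthesis had one of 0.26 (1 of 24 rose, 0 fell; 1 and 0 adjusted over the list alone; adjusted p = 0.0271). Immediate early genes had a median of 0.17 (0 of 24 passed, 9 unadjusted; 2 and 0 adjusted over the list alone; adjusted p = 0.0499). Ribosomal proteins had a median of -0.08 (0 of 80 passed, 4 unadjusted; 0 and 0 adjusted over the list alone; adjusted p = 0.00291), but of 0.04, 0.04 and 0.05 under normexp, quantile normalization and the authors' table. In the order given, the adjusted p was 0.187, 0.242, 0.410, 0.724, 0.284, 0.469, 0.483 and 0.705 with an estimated correlation, and 0.0811, 0.128, 0.367, 0.866, 0.0804, 0.940, 0.448 and 0.148 with slide as a block. Within slide 2, which gives the same fold changes as the block, it was 0.0636, 0.162, 0.526, 0.526, 0.0737, 0.853, 0.415 and 0.169. Over the camera alternatives the lowest were 6.31e-07, 3.25e-05, 6.95e-05, 2.12e-07, 0.00196, 0.00619, 0.00675 and 2.94e-05, and the highest 0.187, 0.242, 0.526, 0.938, 0.284, 0.940, 0.483 and 0.705. The interferon median was 0.07 with slide as a block and 0.01 without normal Se GD replicate 3, where the direction of its test turned, and 0.55 without normal Se GD replicate 2. Without low Se GD replicate 1 the stromal and macrophage medians were 0.20 and 0.19, and the calls of cholesterol synthesis genes (0.16, adjusted p = 0.182) and ribosomal proteins (-0.03, adjusted p = 0.150) were lost. Without normal Se GD replicate 3 macrophage markers (0.18, adjusted p = 0.181), cholesterol synthesis genes (0.19, adjusted p = 0.362) and immediate early genes (0.20, adjusted p = 0.461) did not pass. The immediate early list also did not pass without any 1 of the low Se non-GD arrays (adjusted p = 0.0638, 0.0600 and 0.0595 for replicates 1 to 3, at 0.17 each). The same held for it without low Se GD replicate 2 (0.18, adjusted p = 0.0501) or 3 (0.12, adjusted p = 0.119) and without normal Se GD replicate 1 (0.20, adjusted p = 0.0591).

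**Figure D3:**
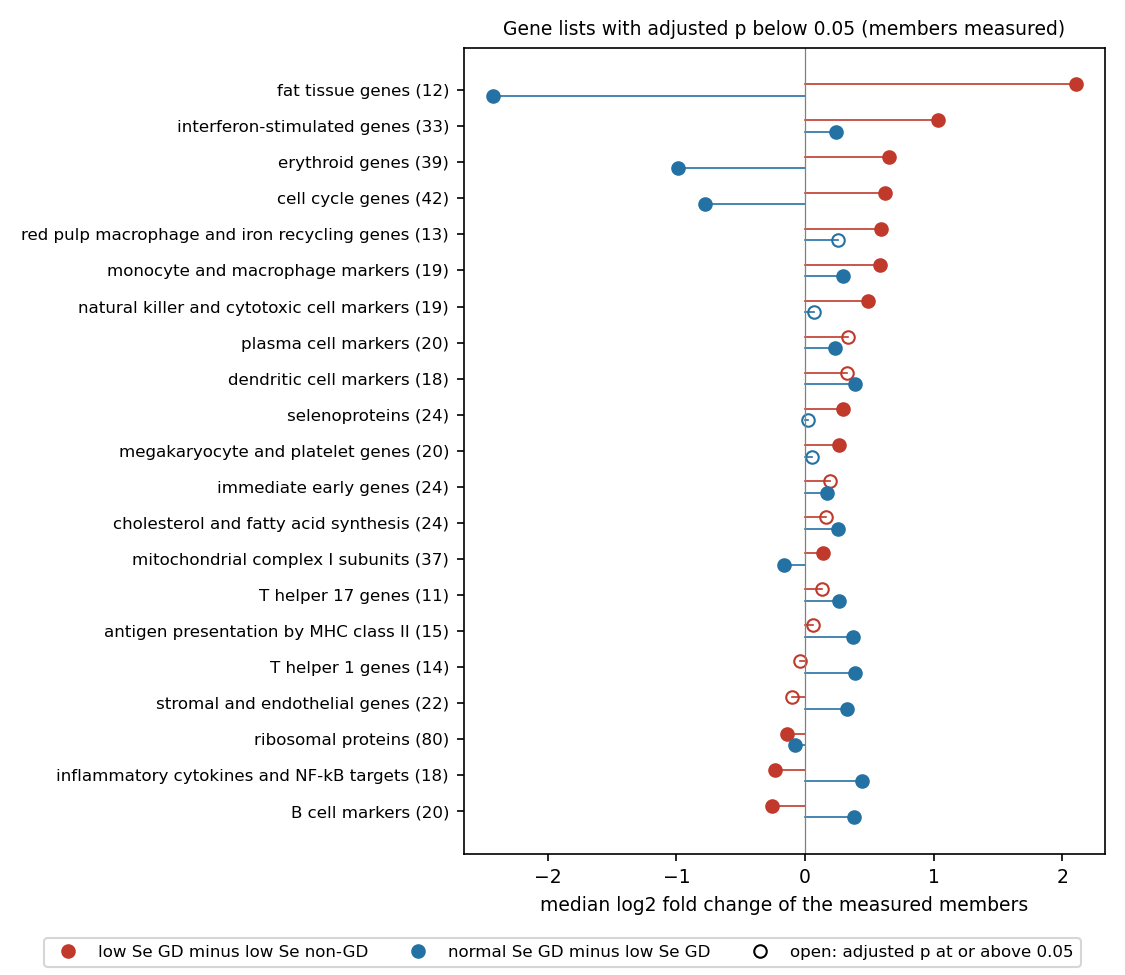
Points give the median log2 fold change of the measured members of each list, for low Se GD minus low Se non-GD (red) and normal Se GD minus low Se GD (blue). They are filled where the camera adjusted p was below 0.05 at the preset correlation of 0.01. With an estimated correlation 0 lists passed in either comparison. B cell markers stood at -0.26 and 0.38, erythroid genes at 0.66 and -0.99, cell cycle genes at 0.63 and -0.78, and ribosomal proteins at -0.14 and -0.08, the last with signs that turned under normexp, quantile normalization and the authors' table.

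Among lists that did not pass, thyroid hormone signalling had a median of -0.17 (adjusted p = 0.150). In it the receptor Thra fell by 0.63 (SE 0.11, adjusted p = 0.0448), with its other probe at -0.03 and not called. T helper 2 genes had a median of 0.22, a mean of -0.02 and an adjusted p of 0.630. The interleukin-4 receptor chain Il4ra fell by 0.61 (adjusted p = 0.0369), with its other probe at -0.09 and not called. NRF2 targets had a median of -0.05 (adjusted p = 0.556), with Abcc1 at 0.47 (adjusted p = 0.0448), and the stress response list -0.09 (adjusted p = 0.0739), with Trib3 at -0.69 (adjusted p = 0.0438). Red pulp genes had a median of 0.26 (adjusted p = 0.643), with Treml4 at 0.80 (adjusted p = 0.0448), and the mast cell list 0.01 (adjusted p = 0.322), with Cpa3 at 0.96 (adjusted p = 0.0451). No member of the other lists passed in this comparison. Their medians and adjusted p were 0.12 and 0.128 for circadian clock genes, 0.19 and 0.128 for regulatory T cells and 0.06 and 0.210 for follicular helper genes. They were 0.06 and 0.822 for T cell markers, 0.13 and 0.193 for germinal centre B cells, and 0.16 and 0.193 for neutrophils. They were 0.07 and 0.322 for natural killer cells, 0.05 and 0.708 for megakaryocytes, 0.16 and 0.222 for complement, and -0.01 and 0.871 for pancreas, whose mean was 0.02.

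Across all genes 334 of 26325 passed, 257 higher (76.9%, or 65.7% with normexp) and 77 lower, with adjusted p no lower than 0.0369, 5112 at an unadjusted p under the threshold, and groups that did not overlap for 29.4% of genes against 10% by chance. The largest higher genes by the rule were Cd163l1, a scavenger receptor (1.31, SE 0.15, adjusted p = 0.0369), the mast cell protease Mcpt1 (1.29, above background on 2 of 3 arrays of each group) and Grpr (1.23, above background on 2 normal Se GD and 1 low Se GD arrays). They were followed by Lilr4b (1.21), Supt7l (1.20), Sv2a (1.16), Tmem220 (1.15) and the plasminogen activator Plau (1.09, SE 0.16, adjusted p = 0.0411), and by Kcnj6 (1.09), Cabp4 (1.05), Pak1 (1.02) and Kynu, an enzyme of tryptophan breakdown (1.02). Besides Adipoq, the lower genes were Cyp2f2 (at least 10.04-fold, adjusted p = 0.0427), Ccdc92b (-1.84), Fam229a (-1.70), Mup2 (-1.64) and the insulin-responsive glucose transporter Slc2a4 (-1.41, SE 0.25, adjusted p = 0.0448). They included pyruvate carboxylase Pcx (-1.24, SE 0.17, adjusted p = 0.0373), H3c1 (-1.14), Ppp1r15a (-1.06), Art4 (-1.05), Nudt4 (-1.01) and the histone H4c11 (-0.996). The other Art4 probe stood at -0.08 and was not called. Without any 1 of 8 arrays the limma count was 0, or 1 without low Se non-GD replicate 2 (3419 to 5163 unadjusted), and without normal Se GD replicate 3 it was 1076. It was 1713 with slide as a block, 2794 within slide 2 and 0 without the 2 in-between arrays (2385 unadjusted), and 46 with quantile normalization or 3 in the authors' table.

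Both comparisons share the 3 low Se GD arrays, with opposite sign. Of the genes past the threshold in both, 67 were lower in low Se GD than in low Se non-GD and higher in normal Se GD, 17 were the reverse, and 49 had the same sign. Independent lists of these sizes would share 41.0 genes of opposite and 42.1 of the same sign. Unchanged groups sharing those arrays gave 0 of either in 50 simulations, but also at most 1 call in a comparison, so that this value was fixed beforehand and gives nothing to set the overlap against. Across genes, which are not independent replicates, the log2 fold changes correlated at -0.134 and their covariance was -0.0521. The simulated means were -0.498 and -0.0558, a difference in covariance of 0.00371. The simulated covariances ran from -0.0591 to -0.0516, a range that holds the observed one. The shared arrays alone could thus give the opposite movement seen across genes. With 3 shared arrays these could not be split, so part or all of the overlap may come from them. With slide as a block 352 were opposite and 366 of the same sign, and with quantile normalization 14 and 13, so that opposite calls did not clearly outnumber the others there.

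The third comparison, normal Se GD against low Se non-GD, differed in both disease and selenium and isolates neither. As lists, interferon-stimulated genes and markers of macrophages, dendritic cells and plasma cells were higher in normal Se GD. None of these 4 lists passed with an estimated correlation (adjusted p = 0.736 for interferon-stimulated genes and 0.370 for each of the others). Ifit3 rose by 3.17 (SE 0.35, adjusted p = 0.00101), Ifit1 by 3.0 (SE 0.29, adjusted p = 0.000635) and Irf7, a master regulator of interferon genes, by 3.24 (SE 0.44, adjusted p = 0.00180). Siglec1, a sialic acid receptor of macrophages, rose by 1.97 (SE 0.24, adjusted p = 0.00140), Itgax by 1.11 (SE 0.10, adjusted p = 0.000525) and Xbp1 by 1.11 (SE 0.14, adjusted p = 0.00134).

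Of 33 interferon-stimulated genes 26 rose and 1 fell (28 and 1 adjusted over the list alone; median 1.28, adjusted p = 4.19e-08). Macrophage markers (13 of 19 rose, 1 fell; 14 and 2 adjusted over the list alone; median 0.82, adjusted p = 0.000244) included C1qa (1.62). Dendritic cell markers (9 of 18 rose, 0 fell; 9 and 1 adjusted over the list alone; median 0.43, adjusted p = 0.00173) included the growth factor receptor Flt3 (1.14). The other Flt3 probe stood at 0.26 and was not called. Plasma cell markers (11 of 20 rose, 0 fell; 11 and 0 adjusted over the list alone; median 0.57, adjusted p = 0.00353) included the chaperone cofactor Sdf2l1 (1.57) and Jchain, the joining chain of secreted antibodies (1.002). Natural killer markers (11 of 19 rose, 1 fell; 13 and 2 adjusted over the list alone; median 0.75, adjusted p = 0.0103) included Klrk1 (1.36). Red pulp genes (8 of 13 rose, 0 fell; 9 and 0 adjusted over the list alone; median 0.74, or 0.51 with 1 member at its bound, adjusted p = 0.0192) included Hpgd (1.23). Megakaryocyte genes (7 of 20 rose, 0 fell; 7 and 0 adjusted over the list alone; median 0.32, adjusted p = 0.0292) included Ppbp (1.38). Ribosomal proteins shifted by -0.19 (6 of 80 rose and 16 fell; 5 and 13 adjusted over the list alone; adjusted p = 0.000244), but by 0.27, 0.28 and 0.31 under normexp, quantile normalization and the authors' table. With an estimated correlation the adjusted p of these 8 lists was 0.736, 0.370, 0.370, 0.370, 0.370, 0.769, 0.822 and 0.770, and with slide as a block 0.000540, 0.112, 0.0535, 0.142, 0.375, 0.402, 0.926 and 0.375. No normal Se GD array shared a slide with a low Se non-GD array, so that the values with slide as a block run wholly through low Se GD replicate 1 in this comparison. Without normal Se GD replicate 3 the calls of natural killer markers (0.66, adjusted p = 0.0664), red pulp genes (0.69, adjusted p = 0.183) and megakaryocyte genes (0.29, adjusted p = 0.335) were lost, the last also without low Se non-GD replicate 2 (0.22, adjusted p = 0.0903). Over the camera alternatives the lowest were 1.82e-12, 7.96e-05, 0.000392, 0.000558, 0.00466, 0.000766, 0.00286 and 1.17e-05, and the highest 0.736, 0.370, 0.370, 0.370, 0.375, 0.769, 0.926 and 0.770. B cell markers, which were lower as a list in the first comparison and higher in the second, had a median of 0.00 here (3 of 20 rose, 2 fell; 2 and 1 adjusted over the list alone; adjusted p = 0.945). The median was -0.35 for erythroid genes (adjusted p = 0.0929), -0.24 for cell cycle genes (adjusted p = 0.0929), -1.04 for fat tissue genes (adjusted p = 0.219) and 0.28 for selenoproteins (9 of 24 rose, 1 fell; 9 and 1 adjusted over the list alone; adjusted p = 0.0929).

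Among all genes 8514 of 26325 passed, 4980 higher and 3534 lower, with 109 at least 4-fold higher and 1313 at least 4-fold lower by the fitted value. Of these, 56 and 40 were above background on no array of the dimmer group, and with bounds in place of fitted values the numbers were 55 and 1282. Rn28s1 (4.90, SE 0.59, adjusted p = 0.00131), Cbr2 (4.26, SE 0.33), Trhr2 (3.91, SE 1.05), Wwc1 (3.88, SE 0.74) and Gfra4 (3.81) were among the largest higher genes, with Sh3bp5 (3.08), Ddx23 (2.98) and Ifit3b (2.83), while Slc35e3 (at least 3.14-fold), not well above background in low Se non-GD, has no rank. The largest lower genes included Olfr71 (-5.00, SE 0.79), Syt14 (-4.94), Gmps (-4.90, with 2 of its 3 probes called higher), the calcitonin receptor Calcr (-4.84), Phlpp2 (-4.66, with its other probe at 0.27 and not called), Prss32 (-4.65), Olfr819 (-4.65), Papolb (-4.63), Btg4 (-4.62), Skint1 (-4.58) and Slc24a2 (-4.56, with its other probe at 0.51 and not called). As in the first comparison, whether the shift of the ribosomal RNA Rn28s1 bears on the other calls was not tested. Of the 1299 genes at least 4-fold lower in the first comparison 1115 (85.8%) were so here too. Both comparisons use the same 3 low Se non-GD arrays, so this overlap is no separate support. The count of 8514 was 4828 with slide as a block, which again rests on low Se GD replicate 1 as the only link between slides, 5415 without low Se non-GD replicate 3 and 3044 without the 2 in-between arrays.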

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

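All tests of an explanation in this part were chosen after the patterns were seen, except the counts of other splits of the samples, which were planned.

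Some control spots, which no comparison uses, differed between the groups. The E1A spots a104, a107 and a97 and the control spot ETG10_13482 gave a signal above the negative controls on every low Se non-GD array. Their log2 difference, low Se GD minus low Se non-GD, was -3.61, -3.57, -3.47 and -3.73. In low Se GD a104 and a97 lay only 0.65 and 0.56 above the negative controls, so their differences are limited by the floor. The E1A spots r60_3, a20 and a22, also above background on every low Se non-GD array, changed by -0.45, 0.27 and -0.28. The difference was thus not shared by all E1A spots.

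The 1299 genes with a fitted change of at least 4-fold lower in low Se GD than in low Se non-GD were weighed against slide, against material that also binds the E1A spot, and against disease. Slide as the cause is argued against: over 1462 genes chosen on the other arrays, low Se GD replicate 1, on the slide of the low Se non-GD arrays, lay at a median position of 0.822 from low Se non-GD (0) to low Se GD (1), with quartiles of 0.737 and 0.933. Material that also binds the E1A spot, in larger amount on the low Se non-GD arrays, may account for part of the shift: between arrays of 1 group the genes followed a107 with a median correlation of 0.782 (1-sided exact permutation within groups, p = 0.00463, the smallest that 216 permutations can give). That compares with -0.0651 for genes at least 2-fold higher and 0.176 for genes not past the threshold, while the within-group slope of 0.660 predicts -2.35 of an observed median of -2.91. Disease state stays open, since the E1A levels of the groups are 2.22 apart at the nearest and no array without disease has a low level.

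Low Se non-GD replicate 3 lay between the other 2 arrays of its group for 78.3% of genes and low Se GD replicate 2 for 69.0%, and for 1075 of 1090 and 609 of 627 of those at least 2-fold apart. If RNA of the other 2 samples of the group had been mixed before hybridisation, the mixing share on the linear scale would be equal for genes higher in either parent. The medians differed by at most 0.0719, so a mixed sample remains a candidate explanation. A smaller difference on the linear than on the log2 scale did not single out these arrays. It was also seen for low Se non-GD replicate 2 (0.213 against 0.264) and the normal Se GD arrays, such as replicate 1 (0.00584 against 0.0812). For low Se non-GD replicate 1 and low Se GD replicates 1 and 3 the linear difference was the larger. A graded difference between 3 separate samples that is even on the log2 scale would instead give equal shares on that scale. There the medians differed by at least 0.145, within the interquartile range of the shares, so it stays open as well. A graded difference that adds up on the linear scale would give the same shares as mixing, so the test cannot tell it from mixing. No biological explanation was tested. The tests count every array as a separate sample. Were these 2 arrays mixtures, the SE, SD and p-values of the comparisons would understate the spread between samples.

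The median of the fat tissue list was higher in low Se GD than in both other groups (log2 2.10 for low Se GD minus low Se non-GD and -2.43 for normal Se GD minus low Se GD). Of its 12 members 5 were called higher and 1 lower against low Se non-GD, and 1 higher against normal Se GD. The list passed in neither comparison with an estimated correlation (adjusted p = 0.890 and 0.272), and leaving out any 1 of 3 arrays ended the call against low Se non-GD. Selenium supply stays open: it predicts no difference between groups on the same supply, and a list score per array (median over members of the deviation from each gene's mean) differed there by 1.78, but with 95% limits of 0.10 to 3.47, which reach below the 2-fold difference set as the bound. Low Se GD replicate 3, at 0.12, lay below low Se non-GD replicate 1, at 0.33. Fat attached to some spleens is a hypothesis that the test allows: between arrays of 1 group the other 11 members followed Fabp4 with a median correlation of 0.811 (1-sided exact permutation, p = 0.0278), against at most 0.601 in 1000 random lists of like level. Lipe and Lpl did not follow, at -0.254 and 0.271. Lipe was highest and lowest on the arrays with the highest and lowest E1A spot, so its course need not bear on fat. Of the 12 members, 9 were higher on every low Se GD array than on every normal Se GD array, and a difference with disease was not tested apart from this.

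For each comparison the 6 arrays can be split into 10 pairs of groups of 3, too few for a share under 0.05. The real split gave 6556, 334 and 8514 genes and every other split 0, so that 1 split of 10 reached the count in each comparison. Every other split mixes arrays of the 2 groups, so the group difference enters its spread. Few or no calls are to be expected there, and the counts of 0 lend little support to the real ones. For gene lists, 3, 4 and 7 of the 10 splits, the real one included, gave as many as the real 13, 17 and 8, with at most 16, 19 and 18 in another split. The cause was not tested.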

How the results depend on the processing

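The settings that left out doubted arrays, ran within a slide, used the E1A spot as a covariate or slide as a random block were chosen after the data were seen, as were the gene-by-gene array weights. Where a result changed, the cause was not tested, except that fewer arrays or genes were used in some settings. The first, second and the third comparison called 6556, 334 and 8514 genes. Array weights gave 21572, 11533 and 18800 (13724, 24678 and 13712 by the default that did not converge), a 2-fold minimum 2829, 41 and 3408, and a 2-fold minimum on the unadjusted p 3307 in the first and 3771 in the third. Without the in-between arrays the counts were 269, 0 (2385 unadjusted) and 3044, and without these and the dimmest array 2929, 0 (3460 unadjusted) and 5553. In the first comparison 940 passed within slide 1, and in the third 4828 with slide as a block. The second gave 46 with quantile normalization, 691 with the percentile over probes above background, 3 from the authors' table, and 0 with no filter (5565 unadjusted). It gave 1288 above background on all arrays, 695 over all probes, and 0 with only the 2 groups (4514 unadjusted). It gave 1713 with slide as a block, 1939 as a random block (consensus correlation 0.721), 2794 within slide 2 and 595 with the E1A covariate, which leaves fold changes as they are. In it 76.9% were higher, 65.7% with normexp, 66.7% in the authors' table, 62.5% with array weights, 54.7% within slide 2, and 43.7% (193 against 249 lower) at a 2-fold minimum on the unadjusted p. With the replicate block it gave 0 (4390 unadjusted), and 5150 and 7186 in the others. The block used the labels' numbers, by which 0 of 9 same-numbered pairs correlated above 0.1 (-0.213 to 0.0991). By the numbers of the authors' table, which differ for low Se non-GD, 4 of 9 did (-0.0143 to 0.236), so that pairing was not settled. Without 1 array the counts ranged from 3448 to 10787, 0 to 1076 and 5415 to 11538, and passing lists from 5 to 15, 14 to 19 and 5 to 13. Lists numbered 13, 17 and 8. In the first comparison 7 passed above background on all arrays, 6 with only the 2 groups, 7 with array weights, 4 with slide as a block, 3 without in-between and dimmest arrays and 3 within slide 1. In the second 10 passed with slide as a block and 11 within slide 2, and in the third 5 above background on all arrays, 3 with slide as a block, 5 without in-between and dimmest arrays and 20 with fry. An estimated correlation left 0 in each. Opposite calls in the first 2 comparisons numbered 84 (49 of the same sign), but 14 (13) with quantile normalization, 320 (197) above background on all arrays, 352 (366) with slide as a block and 0 (0) without in-between and dimmest arrays. Ribosomal proteins turned to 0.25, 0.28 and 0.29 in the first, 0.0420, 0.0403 and 0.0532 in the second and 0.27, 0.28 and 0.31 in the third with normexp, quantile and the authors' table, and Rpl22 in the third to 0.0300, 0.00808 and 0.0320. In the second the interferon list's test turned with slide as a block (0.0705), within slide 2 (0.0705) and without in-between and dimmest arrays (0.0131), and its median ranged from 0.0123 to 0.550 without 1 array, with the test turned in the run without normal Se GD replicate 3. In the same comparison megakaryocyte genes passed at -0.10 within slide 2. In the third megakaryocyte genes turned with slide as a block (0.0487) and selenoprotein synthesis genes, with a median of 0.14, a mean of -0.04 and a camera test pointing down, passed fry upward at 0.14. With probes averaged, Eaf2 and Klra8 turned in the first to 0.14 and -0.0315. Of 149, 44 and 58 named genes that passed, alternatives made 711, 683 and 55 values lose the call, and 2, 0 and 27 genes kept it throughout. The dimmest array, with 58.4% of spots above background, limits what can be said of dim genes.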

Other observations

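The gene lists of this part were fixed and tested as planned, and the counts of receptor genes were chosen after the results were seen. Of 21 genes of heat shock and the unfolded protein response, 7 rose and 2 fell in low Se GD against low Se non-GD (7 and 2 adjusted over the list alone; median 0.12, adjusted p = 0.116 for the list). Among those that rose were the chaperones of the endoplasmic reticulum Calr (1.19, SE 0.10, adjusted p = 0.000492), Pdia4 (1.32) and Dnajb9 (0.95), and Chac1 (1.97), which degrades glutathione. Of 22 stromal and endothelial genes 3 rose and 4 fell (4 and 4 adjusted over the list alone; median -0.10, adjusted p = 0.748). The endothelial cadherin Cdh5 rose by 1.23 (adjusted p = 0.000609), Pdgfra by 1.32 and Stab2 by 0.70, while Cxcl13, the chemokine that draws B cells into follicles, fell by 0.88. Of 13 follicular helper genes 1 rose and 2 fell (1 and 2 adjusted over the list alone; median 0.02, mean -0.18, adjusted p = 0.571). The cytokine Il21 fell by 1.07 (adjusted p = 0.00270) and Pdcd1 by 2.42, and Cd200 rose by 0.82. Pdcd1 was among the 1299 genes at least 4-fold lower, which followed the E1A control spot.

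Among the 1299 genes with a fitted change of at least 4-fold lower in low Se GD than in low Se non-GD were 65 of 477 tested odorant receptor genes and 12 of 124 vomeronasal receptor genes, against 1299 of all 26325 genes. A gene symbol was known for 744 of the 1299, and 3 of them passed between normal Se GD and low Se GD.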
